A study of Homo sapiens with 15 samples.

How the data were processed

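Gene expression was measured in SKOV3ip1, a human epithelial ovarian cancer cell line, on Affymetrix U133 Plus 2.0 arrays, which read each transcript through probe sets placed mostly near its 3′ end. Per the labels, each of 5 conditions was 1 cell growth that gave 1 RNA extract, and 3 aliquots of that extract were hybridised, for 15 arrays. The 3 arrays of a condition are therefore technical repeats of 1 extract. RNA was isolated with Trizol and labelled as biotinylated cRNA by the standard Affymetrix protocol, per the labels' protocols.

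The deposited values are log2 expression per probe set on a scale shared by the arrays. They ran from 4.00 to 15.5. The summary and normalization methods used by the authors are not given in the sources used here. The lower end near 4 would fit a constant of 16 added before the log, and no source states one, so differences of dim genes may be understated on this scale. The deposited log2 values were used without further normalization. Array medians lay between 6.53 and 6.67, and the columns did not share one distribution.

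The table held 54675 probe sets. The 62 control probe sets were left out of all tests. Of the others, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11721 carried none. Symbols were updated through the Entrez identifier, which matched the RefSeq gene table for 41037 probe sets. Each of the 19775 genes was represented by its probe set with the highest mean over the 15 arrays. A gene was tested if the mean of at least 1 extract reached the median of all probe sets (log2 6.60), which left 14369 genes. The probe sets without a symbol were tested only as a count.

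Extracts were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 5 group means fitted to all 15 arrays and 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison together with a difference of at least 1.5-fold. These p-values measure the error of hybridising aliquots of 1 extract. They compare RNA extracts and carry no information on the spread between separate cultures. A second limma fit used the 5 extract means in 3 groups, namely no folate, folate without the 003 antibodies (the folate and 004 cultures) and folate with them (the 003 and MORAb003 cultures), with 2 residual degrees of freedom and no fold minimum. That fit assumes that the 003 and MORAb003 cultures received 1 treatment and that the folate and 004 cultures are equal controls, neither of which the labels state.

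The 28 gene lists were fixed before the data were examined and were tested with camera from limma at its preset correlation of 0.01, and again with a correlation estimated per list. Adjusted p-values of lists are over the 28 lists of a comparison. Where a list's called genes are counted over all 14369 genes, the number adjusted over the list alone is given beside it.

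The genes named were chosen by rules also fixed before the data were examined. FOLR1 was always reported. For folate, genes called between the no-folate and folate extracts were taken if they differed in the same direction from each of the other 3 folate-fed extracts at an adjusted p under 0.05, up to 10 higher and 10 lower. For the antibodies, genes with the same sign and an adjusted p under 0.05 in all 4 differences (the 003 and MORAb003 extracts, each against the 004 and the folate extract) were taken, again up to 10 each way. For the 003 against the MORAb003 extract, and the 004 against the folate extract, the 5 called genes with the largest difference each way were taken. Within a list, up to 4 called members with the largest difference were named, and any member could serve as an uncalled example.

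The fits were tested on simulated data built on the 14369 genes. For the no-folate against folate comparison, 80 of 100 genes changed 1.8-fold and 99 of 100 changed 3-fold were recovered, with 6 false calls. At the culture level, for the antibody contrast, 190 of 200 genes changed 3-fold were recovered with 14 false calls, and 200 of 200 changed 8-fold with 21 false calls. These recoveries hold for the errors that were simulated. Whether those errors match the spread of the real arrays and cultures was not tested. The recovery at the culture level therefore gives no ground to read an absence of called genes as an absence of 3-fold changes. Precision is limited by the number of arrays and, for any statement on a condition, by its single culture.

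Alternatives set before the data were examined were quantile normalization, no filter and a stricter filter on dim probe sets (75th percentile), the mean of all probe sets of a gene, no fold minimum and a 2-fold minimum, the replicate number or the array date as a block, only the 6 arrays compared, another variance prior, an estimated correlation for the lists, the extract as a random block, and leaving out each array, replicate number or culture. The array labelled as replicate 1 of the 004 extract stood apart from its own extract, so all results were also computed without it, on 14 arrays. That choice and the use of array weights were added after seeing the data. The labels place replicates 1 and 2 of every extract on one date and replicate 3 on a later one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.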

Results

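The series measured messenger RNA in SKOV3ip1 ovarian cancer cells, which carry abundant folate receptor alpha (FOLR1), under 5 conditions with 3 arrays each. One culture was kept in folate-free medium for 7 days. The other 4 were kept for 7 days in medium with folic acid at 2 to 10 nM (written nm in the labels), and sample titles of the series use a different abbreviation for the folate source. Of these 4, 1 received no antibody, 1 received the control antibody 004, 1 the antibody labelled 003 and 1 the antibody labelled MORAb003, each for 24 hours. MORAb-003 is an antibody against folate receptor alpha. The labels do not say whether 003 and MORAb003 are the same antibody, and the 2 extracts were kept apart. All p-values between extracts below rest on 3 hybridised aliquots of 1 RNA extract per condition and describe differences between those extracts.

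The RNA of the 5 extracts differed in the control probe sets that compare the 3′ and 5′ ends of long-lived transcripts. The actin 3′ signal exceeded the 5′ signal by log2 4.09 ± 0.16 (SD, n = 3 arrays) in the no-folate extract and 4.02 ± 0.10 in the 003 extract. The gap was 3.24 ± 0.13 in the folate extract, 3.46 ± 0.31 in the 004 extract and 2.42 ± 0.13 in the MORAb003 extract. The GAPDH gap was 2.37 ± 0.12, 2.49 ± 0.03, 1.97 ± 0.05, 2.05 ± 0.27 and 1.21 ± 0.14 in the same order of no-folate, 003, folate, 004 and MORAb003. A larger gap is a usual sign of shorter or partly degraded RNA. Arrays of 1 extract correlated across probe sets at 0.993 to 0.998, except replicate 1 of the 004 extract, which correlated with its own extract at no more than 0.95 and whose 90th percentile was log2 9.04 against 9.73 and 9.74 in the 2 other 004 arrays.

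**Figure D1:**
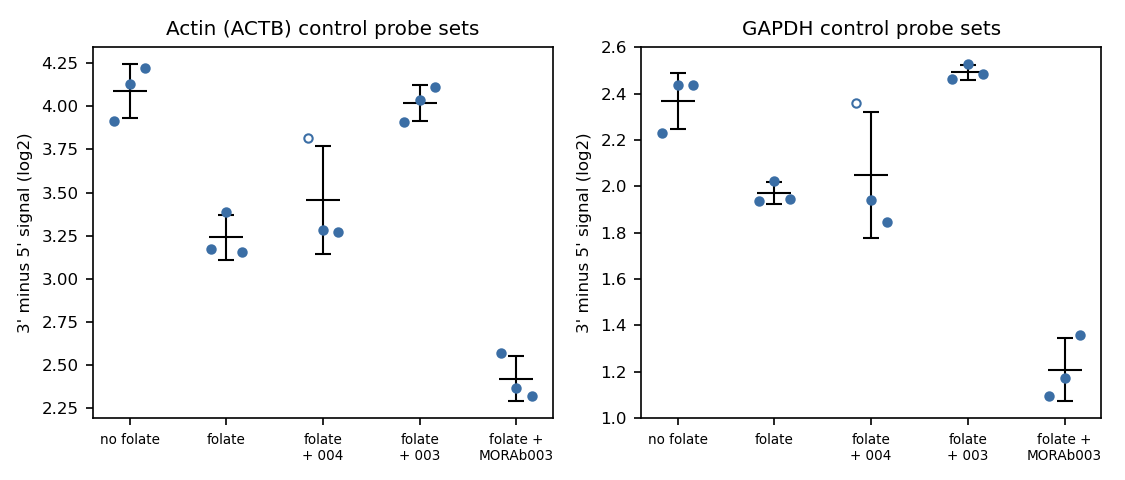
Difference between the 3′ and 5′ control probe sets of actin and GAPDH (log2) on each array, by extract; points are arrays, the open point is replicate 1 of the 004 extract, and bars are the mean ± SD of 3 arrays. The actin gap of the no-folate and 003 extracts lies at 4.09 and 4.02 and that of the MORAb003 extract at 2.42.

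FOLR1, the gene of the target of MORAb-003 and a high-affinity folate receptor, read log2 13.80 ± 0.11 (SD, n = 3 arrays) without folate, 13.53 ± 0.09 with folate, 13.51 ± 0.29 with 004, 13.79 ± 0.05 with 003 and 14.06 ± 0.04 with MORAb003. FOLR1 was higher in the MORAb003 than in the folate extract by 0.53 (SE 0.13, adjusted p = 0.0178). It was higher than in the 004 extract by 0.55 (SE 0.13, adjusted p = 0.00633), or by 0.39 with an adjusted p of 0.00206 without replicate 1 of the 004 extract. All of these were under the 1.5-fold minimum. The no-folate and folate extracts differed by 0.27 (SE 0.13, adjusted p = 0.281, or 0.0154 without replicate 1 of the 004 extract), and the 003 and 004 extracts by 0.29 (SE 0.13, adjusted p = 0.207, or 0.12 with an adjusted p of 0.314 without that array). Between the 003 and folate extracts FOLR1 differed by 0.27 (adjusted p = 0.246, or 0.015 without that array).

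The first comparison asked how gene expression differed between cells without and with folate. In the no-folate extract 7 of 18 genes of cholesterol synthesis and uptake and 2 of 12 of fatty acid synthesis were lower than in the folate extract, with an adjusted p = 0.925 for each list with an estimated correlation. SCD, the stearoyl-CoA desaturase, fell by 1.5 (log2, SE 0.18, adjusted p = 0.0024). STARD4, a cholesterol transporter, fell by 1.20 (adjusted p = 0.00563), and SC5D and SQLE, enzymes of cholesterol synthesis, fell by 1.15 and 0.91. SCD, STARD4 and SC5D were also lower in the folate-fed 003 extract than in the folate extract, at -0.95, -1.13 and -0.99. Their fall was therefore not limited to the lack of folate. In the MORAb003 extract SCD and STARD4 were higher than in the folate extract, at 0.73 and 0.98. The mitochondrially encoded ND2 fell by 1.14 (SE 0.10, adjusted p = 0.000222) and ATP6 fell by 1.00 (SE 0.10, adjusted p = 0.000432), and both were also lower than in each of the other 3 folate-fed extracts. Against the folate extract ND2 was also lower with 003 and MORAb003, at -0.44 and -0.42 (adjusted p = 0.0305 and 0.017). ATP6 was lower with MORAb003, at -0.45 (adjusted p = 0.00968), and differed by -0.20 with 003 (adjusted p = 0.238). Smaller falls of these genes thus also occurred with folate present. AGAP4, the pseudogene ZDHHC8BP, MIB2 and IGFBP6, a binding protein of insulin-like growth factors, rose by 0.91, 0.80, 0.79 and 0.73 with adjusted p-values of 0.0027, 0.0024, 0.00815 and 0.0036, and were likewise higher than in each other folate-fed extract. No other gene met that rule.

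Among the lists fixed beforehand, 6 of 28 were called, all lower without folate. Of 35 measured genes of G2/M and mitosis, 6 fell (11 adjusted over the list alone), with ANLN at -0.94, KIF11 at -0.80, KIF20A at -0.80 and CDK1 at -0.73, and the list's median was -0.395 (adjusted p = 2.34e-08). Cholesterol synthesis and uptake had 7 of 18 genes lower (8 adjusted over the list alone) and a median of -0.248 (adjusted p = 0.000327). Fatty acid synthesis had 2 of 12 lower (3 adjusted over the list alone, adjusted p = 0.0234). Hypoxia and glycolysis had 3 of 31 lower (5 adjusted over the list alone, adjusted p = 0.000327), namely BNIP3, ALDOC and P4HA1 at -0.85, -0.73 and -0.68. The endoplasmic reticulum chaperones PDIA3 and HSPA5 fell by 0.72 and 0.66, as 2 of 21 genes of their list (4 adjusted over the list alone, median -0.380, adjusted p = 6.49e-08). Heat shock genes were called as a list (median -0.160, adjusted p = 0.0192) with 0 of 11 genes called over all genes and 0 adjusted over the list alone. For each of these 6 lists the adjusted p = 0.925 with an estimated correlation. These lists moved together with an actin 3′ to 5′ gap that was larger by log2 0.85 without folate. BNIP3, ALDOC, P4HA1 and PDIA3 were also lower in the folate-fed 003 extract than in the folate extract, at -1.07, -1.08, -0.97 and -0.86.

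Of 8 genes of folate uptake and retention, GGH, a folylpolyglutamate hydrolase, fell by 0.75 (adjusted p = 0.0277; 1 adjusted over the list alone), and of 21 genes of folate one-carbon metabolism MAT2B fell by 0.82 (adjusted p = 0.0102; 1 adjusted over the list alone). Neither list was called (adjusted p = 0.645 and 0.154). GGH and MAT2B were also lower in the folate-fed 003 extract than in the folate extract, at -0.80 and -0.79. Of 16 epithelial and ovarian cancer genes, MUC1, an epithelial mucin, rose by 1.08 (adjusted p = 0.0027), CLDN4 rose by 0.61 (adjusted p = 0.0348) and OCLN fell by 0.70 (adjusted p = 0.0498; 2 higher and 2 lower adjusted over the list alone), and the list was not called (adjusted p = 0.1). Fibroblast and endothelial markers and leukocyte markers had 0 of 11 and 0 of 9 genes called (0 and 0 adjusted over the list alone).

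In all, 389 of 14369 genes were called between the no-folate and folate extracts, 130 higher and 259 lower. Without replicate 1 of the 004 extract, which enters this comparison only through the shared error, 922 were called, 191 higher and 731 lower, with all 389 among them. Leaving out other single arrays gave as few as 91. The first array date alone, with 2 arrays per extract, called 0.

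The antibody comparisons set the 003 and MORAb003 extracts against the control antibody 004 and against folate alone. A small set of genes moved the same way in both antibody extracts against both controls, at an adjusted p under 0.05 and with no fold minimum. SLPI, a secreted protease inhibitor, rose by 0.99 (SE 0.12, adjusted p = 0.00315) with 003 and by 1.11 (SE 0.12, adjusted p = 8.35e-05) with MORAb003 against the 004 extract, and by 0.89 and 1.01 against the folate extract. PI3, a related inhibitor of elastase, rose by 0.48 and 0.73 against 004. MACROD1 rose by 1.01 and 1.31, PTGDS, a prostaglandin D synthase, by 1.24 and 0.65, CYBA, a subunit of NADPH oxidase, by 0.72 and 0.85, and MAP3K14, the kinase of the noncanonical NF-kB pathway, by 0.76 and 0.56. CCDC124 rose by 1.03 and 0.74, TCL1B by 0.73 and 0.34 and SCGB1D2 by 0.43 and 0.36. The proteolipid MAL fell by 0.59 (SE 0.12, adjusted p = 0.0173) and 0.79 (SE 0.12, adjusted p = 0.000688), SERINC2 fell by 0.51 and 0.35, and PDIA3 fell by 0.70 and 0.53.

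These 9 higher and 3 lower genes were all that met the rule. SLPI, MACROD1, CYBA, PI3, PTGDS and TCL1B were also higher in the no-folate than in the folate extract, by 0.68, 1.14, 0.75, 0.55, 0.54 and 0.70, with adjusted p-values from 0.00134 to 0.011, so their rise was not limited to antibody. MAL read 12.81 without folate and 12.70 with it, against 11.97 with 003 and 11.77 with MORAb003. With the mean of all probe sets of a gene, PDIA3 differed between the MORAb003 and folate extracts by 0.03 (adjusted p = 0.905), the opposite sign.

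**Figure D2:**
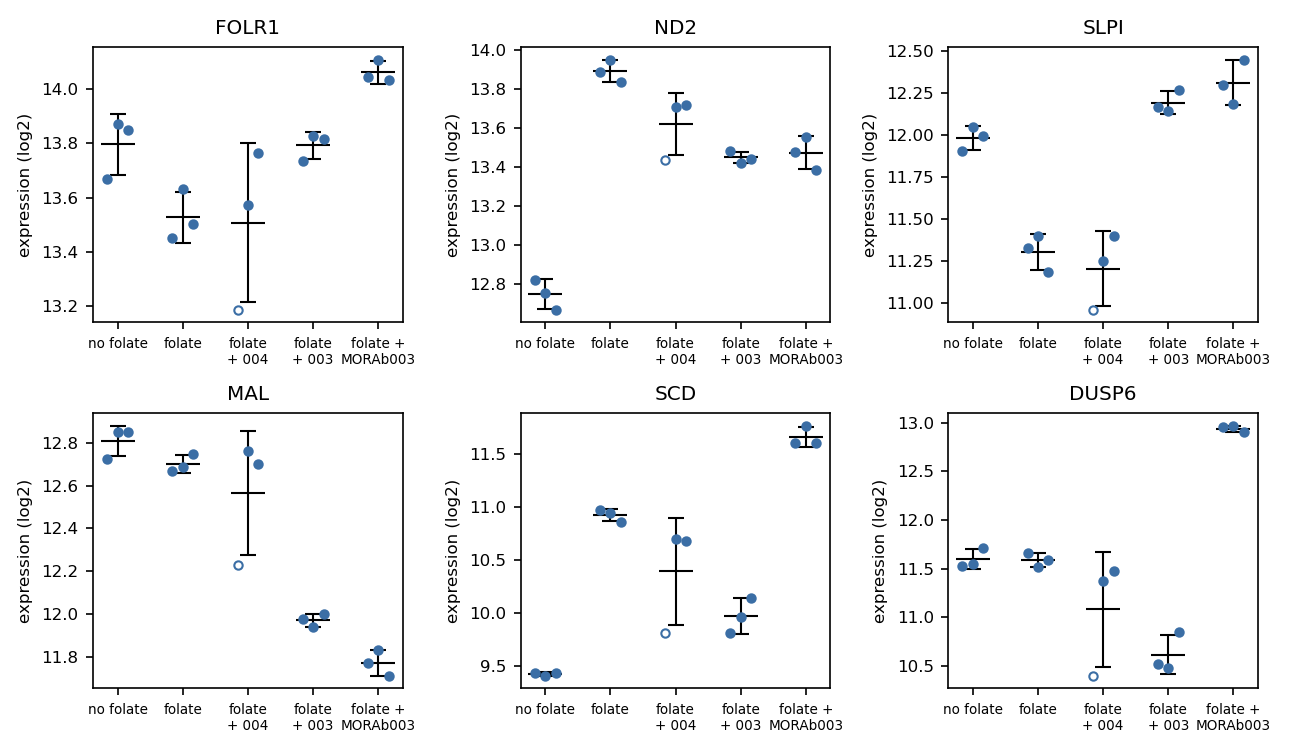
Expression (log2) of 6 genes on each of the 15 arrays by extract; points are arrays, the open point is replicate 1 of the 004 extract, and bars are the mean ± SD of 3 arrays, on axes that do not start at 0. SLPI reads 12.19 with 003 and 12.31 with MORAb003 against 11.30 with folate alone, and SCD and DUSP6 differ in opposite directions in the 003 and MORAb003 extracts.

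In the 003 extract, set against the 004 extract, the NF-kB feedback genes NFKBIA and TNFAIP3 rose by 1.27 (adjusted p = 0.00638) and 0.89 (adjusted p = 0.0296), as 2 of 17 genes of NF-kB and cytokines (2 adjusted over the list alone, list adjusted p = 0.0724). Without replicate 1 of the 004 extract they rose by 1.01 and 0.60 and were still called. Against the folate extract NFKBIA rose by 1.00 (adjusted p = 0.0174) and TNFAIP3 was not called. Again relative to 004, ASNS, the asparagine synthetase, fell by 0.99 and DDIT4 fell by 0.73, while ATF5 of the same amino acid response list rose by 0.61 (0.41 and not called without replicate 1 of the 004 extract; 1 of 36 higher and 2 lower, the same numbers adjusted over the list alone). SPRY2 and SPRY1, feedback inhibitors of receptor tyrosine kinase signalling, fell by 0.98 and 0.69, while KLF6 and FOSL1 of the same list of immediate early and ERK targets rose by 0.74 and 0.65 (0.44 and 0.53, neither called, without that array; 2 of 33 higher and 2 lower, 3 and 2 adjusted over the list alone). Of hypoxia and glycolysis, ALDOC, P4HA1 and BNIP3 fell by 0.90, 0.89 and 0.80, as 3 of 31 genes (3 adjusted over the list alone, list adjusted p = 0.00131). Of 8 genes of folate uptake and retention, SLC19A1, the reduced folate carrier, rose by 0.81 (adjusted p = 0.0173; 0.55 and not called without that array) and GGH fell by 0.62 (adjusted p = 0.0487), with the same 1 higher and 1 lower adjusted over the list alone.

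Hypoxia and glycolysis, the chaperone list (1 of 21 lower, 1 adjusted over the list alone, median -0.260, adjusted p = 0.00529) and the metallothioneins (0 of 7 called, 0 adjusted over the list alone, median -0.253, adjusted p = 0.00131) were the 3 lists called for 003 against 004. For each the adjusted p = 0.98 with an estimated correlation. Without replicate 1 of the 004 extract 8 lists were called, 7 of them lower. With an estimated correlation only 1 was, the metallothioneins, with a median of -0.563 and an adjusted p = 0.0435. The actin 3′ to 5′ gap of the 003 extract exceeded that of the folate extract by 0.78.

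The count of called genes for 003 against 004 was 498, of which 441 were higher and 57 lower. It turned on 1 array: without replicate 1 of the 004 extract 897 genes were called, 114 higher and 783 lower, and 163 were called both ways. A fit of only the 6 arrays compared called 0. So did a fit of the first array date alone, with 2 arrays per extract. After quantile normalization of all 15 arrays 365 were higher and 198 lower. Against the folate extract, 003 gave 290 genes, 62 higher and 228 lower (204 and 423 after quantile normalization), and 1032 without that array, 105 higher and 927 lower, or as few as 1 without another array. Of the lists, 11 were called for 003 against folate, 2 higher and 9 lower, and 0 with an estimated correlation, with the metallothioneins at a median of -0.541 (2 of 7 lower, 3 adjusted over the list alone, adjusted p = 1.86e-05, and adjusted p = 0.694 with an estimated correlation, or 0.0489 without that array).

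In the MORAb003 extract the immediate early and ERK target genes stood out. FOS rose by 1.96 (adjusted p = 2.95e-05), DUSP6, an ERK phosphatase, by 1.86 (SE 0.21, adjusted p = 0.000118), PHLDA1 by 1.51 and SPRY2 by 1.44 against the 004 extract. Of 33 measured genes 19 rose and 0 fell (19 adjusted over the list alone), and the list's median was 0.781 (adjusted p = 7.03e-05, and adjusted p = 0.824 with an estimated correlation). Against the folate extract 10 rose and 0 fell (10 adjusted over the list alone), with a median of 0.381 (adjusted p = 1.02e-05, and adjusted p = 0.907 with an estimated correlation). Within the first array date the median was 0.415 against folate and 0.908 against 004, and within the second, with 1 array per extract, 0.435 and 0.434. Without replicate 1 of the 004 extract 13 of 33 rose against 004, the median was 0.508 and PHLDA1 differed by 0.95.

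Other groups also stood higher with MORAb003 than with 004, in a comparison where 2529 of all 14369 genes were called higher. STARD4 rose by 1.55 and SCD by 1.26, in lists of cholesterol (5 of 18 higher, 5 adjusted over the list alone, adjusted p = 0.0259) and fatty acid synthesis (4 of 12 higher, 4 adjusted over the list alone, adjusted p = 0.0211). The p53 targets RRM2B, TP53INP1 and MDM2 rose by 1.65, 1.29 and 1.26 (7 of 17, 8 adjusted over the list alone, adjusted p = 0.0386). CCNE2 and CDC6 of G1/S and DNA replication rose by 1.40 and 1.38 (9 of 34, 9 adjusted over the list alone, adjusted p = 0.0211). MTFMT and GLDC of folate one-carbon metabolism rose by 1.16 and 0.99 (6 of 21, 7 adjusted over the list alone, adjusted p = 0.0211). DNAJB9 of the chaperone list rose by 1.46 (7 of 21, 7 adjusted over the list alone, adjusted p = 0.0211) and NPC1 of the lysosome by 1.01 (4 of 27, a smaller share than over all genes, 4 adjusted over the list alone, adjusted p = 0.0211). For each of these lists the adjusted p = 0.824 with an estimated correlation, and without replicate 1 of the 004 extract only fatty acid synthesis (adjusted p = 0.0455) and the immediate early list (adjusted p = 1.28e-05) were called, or 0 lists with an estimated correlation. Without that array RRM2B, CDC6 and MTFMT differed by 1.05, 0.84 and 0.63. Against the folate extract the immediate early list was the 1 list called. The actin gap of the MORAb003 extract was the smallest of the 5, at 2.42.

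MORAb003 against 004 gave 2862 called genes, 2529 higher and 333 lower, and 1748 without replicate 1 of the 004 extract, 1407 higher and 341 lower, of which 1505 were called both ways. A fit of only the 6 arrays compared called 25. The first array date alone, with 2 arrays per extract, called 2470, of which 2115 were higher and 355 lower. Quantile normalization gave 1690 higher and 946 lower. Against the folate extract 945 genes were called, 685 higher and 260 lower (602 and 420 after quantile normalization), and 1465 without that array, or as few as 427 without another array.

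**Figure D3:**
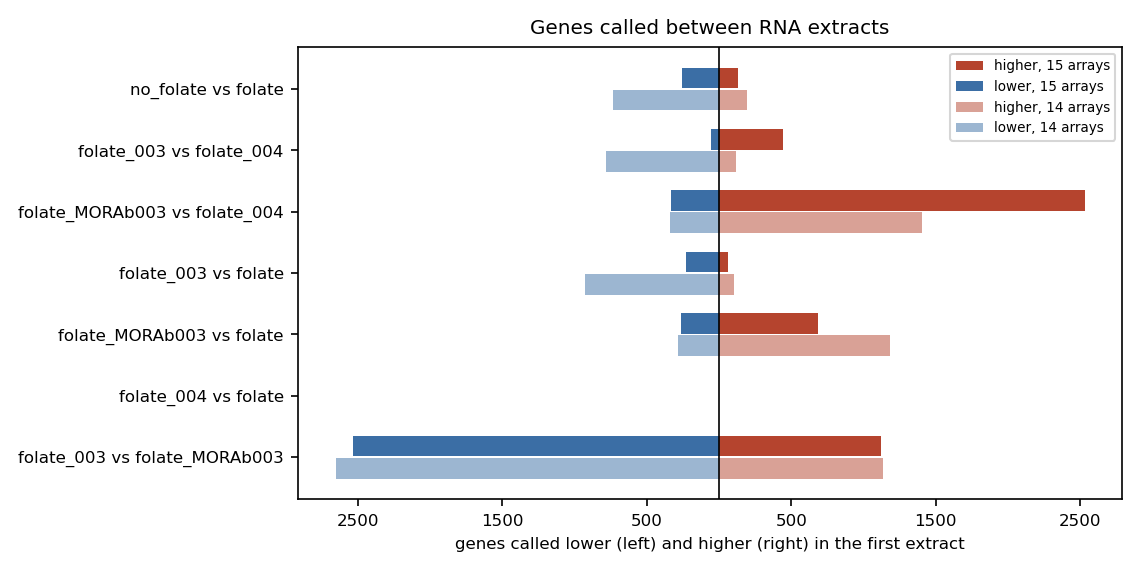
Number of genes called higher (right) and lower (left) in the first extract of each of 7 comparisons, with all 15 arrays (dark) and without replicate 1 of the 004 extract (light). For 003 against 004 the bars change from 441 higher and 57 lower to 114 higher and 783 lower.

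The 2 control extracts, with 004 and with folate alone, differed in 0 of 14369 genes by limma. At an unadjusted p under 0.05 there were 1276 genes, or 481 without replicate 1 of the 004 extract. Leukocyte markers (median 0.255) and 6 lists with negative medians, among them G2/M (-0.232) and cholesterol synthesis (-0.274), were called with 0 member genes called. For all 7 the adjusted p = 0.856 with an estimated correlation. The median of all genes was itself -0.128, and without replicate 1 of the 004 extract that median was 0.01 and 0 lists were called.

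The 2 antibody extracts differed from each other more than either differed from the folate extract. The Wnt receptors FZD7 and FZD6 were lower with 003 than with MORAb003 by log2 -3.48 (SE 0.39, adjusted p = 2.73e-05) and -3.36 (SE 0.35, adjusted p = 1.97e-05), SEMA3C by -2.96, ZPLD1 by -2.80 and CTH, an enzyme of cysteine synthesis, by -2.74. TMEFF2, LRRFIP1, WBP4, NLN and MPHOSPH8 were higher with 003 by 2.12, 2.12, 1.97, 1.82 and 1.77. SPRY2, DUSP6 and FOS differed by -2.42, -2.33 and -2.18, and 16 of 33 genes of their list were lower and 2 higher (the same numbers adjusted over the list alone, adjusted p = 0.00145, and adjusted p = 0.9 with an estimated correlation). The actin and GAPDH gaps of these 2 extracts were 4.02 and 2.49 with 003 against 2.42 and 1.21 with MORAb003, and the bioB spike read 10.82 against 8.74. SCD, at -1.69, and STARD4, at -2.11, also separated the 2. In all 3652 genes were called, 1120 higher and 2532 lower with 003 (1639 and 2011 after quantile normalization).

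Across the 14369 genes, which are not independent replicates, the differences of the 2 antibody extracts ran opposite to each other. The difference of 003 from folate and that of MORAb003 from 004, which share no array, correlated at r = -0.648 (Spearman's rho -0.588). Simulated unchanged extracts gave 0.000806. That simulation drew hybridisation error alone, gene by gene, so an r near 0 was fixed in advance for pairs without a shared array. It does not gauge the observed r against differences between cultures or in RNA integrity. With the controls exchanged r was -0.263, and -0.541 without replicate 1 of the 004 extract. With 004 as the shared control r was -0.0115 (Spearman's rho 0.0686, 54.1% of genes with the same sign), where simulated unchanged extracts gave 0.499, and the covariance was -0.00171 against a simulated 0.0154. Without replicate 1 of the 004 extract that r was -0.480 against a simulated 0.599. Of the genes called lower in 003 against folate, 143 were called higher in MORAb003 against 004, where independent lists would share 40.1 (468 against 90.8 without replicate 1 of the 004 extract). Both called higher numbered 4 against 10.9.

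The size of the differences was also counted between extract means. At least 1.5-fold apart were 138 genes between no folate and 003, 922 between no folate and folate, 1032 between folate and 003, 1465 between folate and MORAb003, 3322 between no folate and MORAb003 and 3784 between 003 and MORAb003. At least 2-fold apart were 7, 77, 97, 257, 1237 and 1430 in that order. The pairs with 004 had 489 (folate), 826 (003), 1110 (no folate) and 3151 (MORAb003) genes at least 1.5-fold apart and 1, 37, 116 and 1127 at least 2-fold apart. Without replicate 1 of the 004 extract these were 1, 898, 943 and 1748 at 1.5-fold and 0, 68, 72 and 370 at 2-fold, and between 004 and 003 the genes higher in 004 went from 146 to 784 and those lower from 680 to 114.

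**Figure D4:**
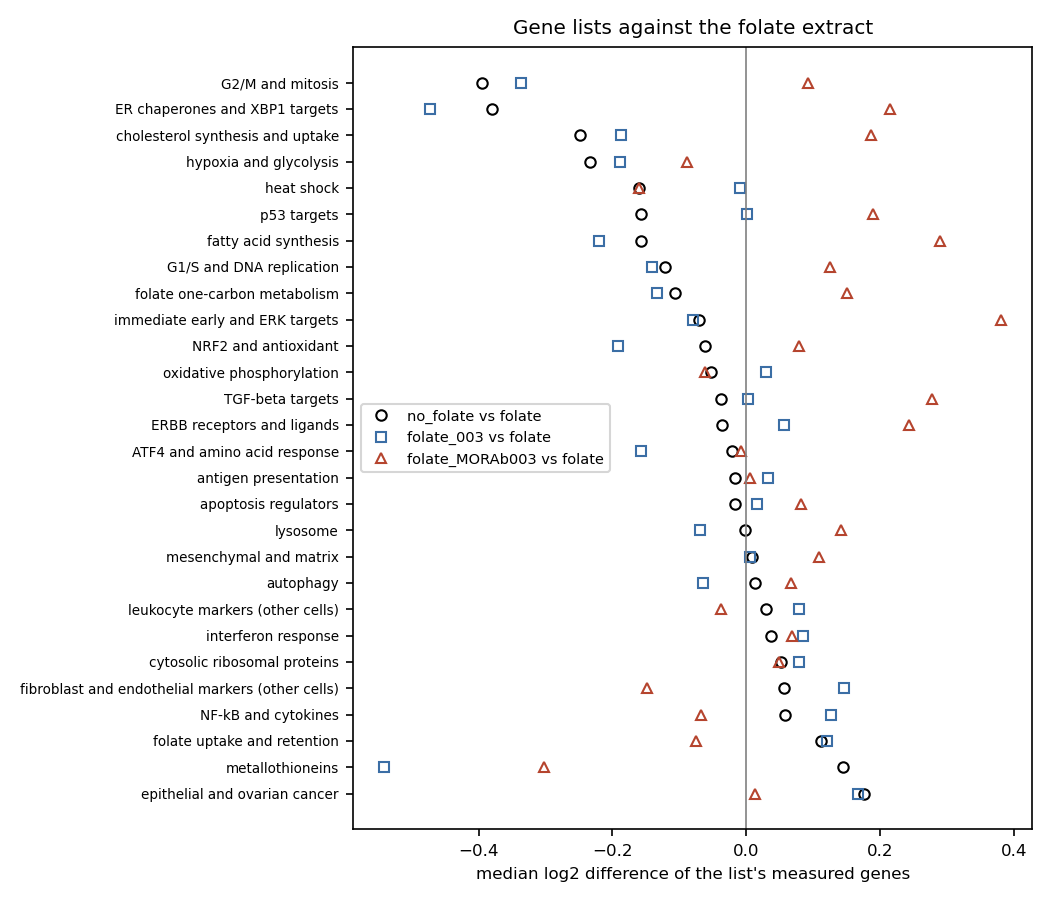
Median log2 difference from the folate extract over the measured genes of each of the 28 lists, for the no-folate (circles), 003 (squares) and MORAb003 (triangles) extracts, all 15 arrays. Immediate early and ERK targets lie at 0.381 with MORAb003, and G2/M and mitosis at -0.395 without folate and -0.337 with 003.

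With separate cultures as the replicates, 0 genes were called by limma for antibody (003 and MORAb003) against no such antibody (folate and 004), and 0 for no folate against those controls. No folate is 1 culture with no replicate, and the spread comes only from the other 2 pairs. Recovery at this level was measured on simulated errors only, so the 0 calls do not show that large changes were absent. At an unadjusted p under 0.05 there were 47 and 127 genes, where chance would give 718, or 113 and 300 without replicate 1 of the 004 extract. The 2 other ways to pair these 4 cultures gave 248 and 2505 genes at an unadjusted p under 0.05 and 0 called (72 and 406 without that array), the higher number with 003 beside 004 and MORAb003 beside folate. SLPI reached an unadjusted p of 0.00246 and MACROD1 0.0039 for antibody, each with an adjusted p of 1. Camera called 6 lists for antibody, with metallothioneins lower (median -0.272, adjusted p = 2.07e-05) and immediate early and ERK targets higher (median 0.228, adjusted p = 0.00204), and adjusted p = 0.882 for each with an estimated correlation. Without replicate 1 of the 004 extract the median of the immediate early list was 0.106, and its median in 003 against folate alone was -0.0801. For no folate it called 5 lists, all lower, with G2/M and mitosis first (median -0.304, adjusted p = 7.57e-06), and adjusted p = 0.977 for each with an estimated correlation.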

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

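The tests of 3′ bias and of shared control arrays in this part were chosen after the values were seen, as were the results without replicate 1 of the 004 extract. The spread rule applied to the other probe sets of the immediate early list was also added after its median was seen. The bound from unrelated probe sets in the RNA integrity test was likewise added after its ratio was seen, and the 3′ bias test of the 004 array was read as undecided only after its r was seen. These 3 changes moved the reading from a decided one to an open one.

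The difference between the 2 antibody extracts stood out because both were set against the same controls and moved apart: 3652 genes were called between them by the test of that difference. Outside the gene measurements, the actin 3′ to 5′ control gap exceeded that of the folate extract by 0.85 without folate and by 0.78 with 003, and the Alu control probe set by 0.23 and 0.19. Of 3953 probe sets with no gene symbol, 199 were called between the no-folate and folate extracts and 180 between the MORAb003 and folate extracts.

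The first pattern is the array labelled replicate 1 of the 004 extract, whose deviation from the 2 other arrays had an SD of 0.611 over probe sets, against 0.186 at most for the other 14 arrays, each compared with its own extract without that array. A 3′ bias of that aliquot stays open: its deviation followed the no-folate difference at r = 0.230 and the difference of 003 from folate at r = 0.370, neither of which is a measured profile of 3′ bias. The actin gap of that array was 3.82 against 3.28 and 3.27 in the 2 others. A change of brightness or range could be removed by quantile normalization, and its lowest correlation with its own extract stayed at 0.949. An otherwise sound aliquot of another extract of the series is argued against. The array's highest correlation with any array was 0.957, where the other arrays of 1 extract correlated at 0.993 or more. The 3 arrays came from 1 extract, so no biological explanation was tested, and a fault in that hybridisation, with or without a mislabelled aliquot, stays open.

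The second pattern is that the 003 and no-folate extracts were displaced from folate alike and the MORAb003 extract the opposite way. Chance from shared control arrays is argued against by r = 0.582 between the no-folate difference from folate and the 003 difference from 004 (0.792 without replicate 1 of the 004 extract). After quantile normalization r was 0.577, which argues against unequal distributions of the deposited columns as the source. Quantile normalization keeps the ranks within an array, so an effect of the authors' unstated summary and normalization stays open. The MORAb003 side is less even: the no-folate difference from folate and the MORAb003 difference from 004 correlated at -0.436, but with the controls exchanged at -0.0380 (and the 003 side at 0.343), or -0.327 and 0.691 without that array. RNA integrity could account for it: the order is that of the 3′ to 5′ gaps, and 2 probe sets of a gene moved apart 2.57 times as widely (SD, no folate against folate) as between 004 and folate without replicate 1 of the 004 extract. That SD of 0.365 stayed under the 0.453 of unrelated probe sets, and true changes that probe sets read unequally would raise it too, so RNA integrity, folate and antibody all stay open, with 1 culture per condition. Among 6290 genes with 2 probe sets, 498 differed at least 1.5-fold between no folate and folate by the brightest one. The next probe set moved the same way in 72.3% of these, by a median of 25.9% of the change. For 003 and MORAb003 against folate these values were 80.4% and 42.6%, and 73.6% and 37%. The size of a single gene's difference thus depends on the probe set chosen.

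The third pattern is the immediate early and ERK target list in the MORAb003 extract. Genes of that brightness did not in general rise as much: the list's median difference from folate of 0.381 lay at percentile 100 of 10000 random lists matched on mean expression, whose 99th percentile was 0.162. The list was looked at because it was called in these same data, and random lists leave out the correlation within it. Its percentile is therefore no separate support for the list. The position of the chosen probe sets stays open: the 36 other probe sets of 18 of its genes had a median of 0.196, close to the bound of 0.19 set beforehand. Over resampled genes this median had a lower bound of 0.00654 and an upper bound of 0.379, which leave out both tails of the resampled values. An effect of MORAb003 on this list may be one explanation, but 1 culture and the low 3′ to 5′ gap of that extract leave it untested.

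Regrouping the 6 arrays of a comparison gives 10 splits, too few for a share under 0.05. Every other split mixes arrays of 2 extracts, which puts the difference between them into the error, so low counts there are nearly fixed in advance. The splits therefore say nothing on chance differences between cultures. The real count and the highest other were 389 and 0 for no folate against folate, 2862 and 0 for MORAb003 against 004, 290 and 0 for 003 against folate, 945 and 0 for MORAb003 against folate, and 3652 and 0 for 003 against MORAb003, with 1 of 10 splits reaching the real count in each. For 004 against folate all 10 gave 0. For 003 against 004, 2 of 10 reached the real 498, and the highest other, 1354, put replicate 1 of the 004 extract with replicates 1 and 2 of 003, which points to the structure of that array. Its real count without the array was 897.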

How the results depend on the processing

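The alternatives were set before the data were examined, except the results without replicate 1 of the 004 extract, array weights, and leaving out a culture together with that array, which were chosen after seeing the data. Counting each result once per alternative, single genes stayed on their side of the threshold 1411 times, lost it with the same sign 615 times, gained it 1 time and reversed 3 times. Single lists stayed 136 times, weakened 77 times and reversed 3 times, and counts and correlations stayed 218 times and moved 139 times. Of 255 single genes, 203 lost the threshold without replicate 2, 163 without replicate 3 and 48 without replicate 1. Only the last of these left out replicate 1 of the 004 extract. The deviation of that array from its extract mean had the largest SD of all arrays (0.450 over genes). Its share in these losses was not tested. The Pearson correlations of the 2 pairs of antibody differences that share no array stayed negative, the second down to -0.0106 without replicate 2, with SDs of 0.166 and 0.313 over replicate numbers. A stricter dim filter, another variance prior and the date block moved no count by more than 1.5 times, and neither did the replicate block, under which 22 of 255 single genes lost the threshold. Replicate numbers did not pair the arrays: deviations correlated from -0.545 to 0.524, with 2, 3 and 3 of 10 pairs over 0.1. The extract as a random block left 0 genes called at the culture level. Genes below the dim filter (log2 6.60) may lie near background, which was not measured here, and this limits what the lists without a filter show.

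Quantile normalization gave 643 called genes for no folate against folate, 627 for 003 against folate, 6, 2 and 0 lists for 003 against 004, MORAb003 against 004 and 004 against folate, 3 lists for no folate at the culture level, and 4 genes 2-fold apart between folate and 004. Without a dim filter the lists were 15 (MORAb003 against 004), 18 (004 against folate), 10 (culture level, antibody) and 3 (culture level, no folate). The cause was not tested. Array weights, whose fit stopped before its convergence tolerance, gave 956 (no folate against folate), 987 and 1900 (003 and MORAb003 against 004), and 1033 and 1606 (against folate). With only the 6 arrays compared these were 919, 0, 25, 1029 and 1465. The cause was not tested.

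By construction, a fold minimum of 2 lowered the counts to 64, 31, 1121, 58, 240 and 1430 (the same order, then 003 against MORAb003), and no minimum raised them to 857, 5046, 441, 1600 and 6412 from 003 against 004 onwards. An estimated correlation left 0 lists in each of the 6 list results. The mean of all probe sets gave 192, 299, 1886, 172 and 551 genes and 3 lists for no folate at the culture level. Its pairs at 1.5-fold and 2-fold were 432 and 33 (no folate, folate), 537 and 26 (no folate, 004), 67 and 3 (no folate, 003), 2088 and 608 (no folate, MORAb003), 139 and 0 (folate, 004), 496 and 48 (folate, 003), 756 and 110 (folate, MORAb003), 436 and 12 (004, 003), 2002 and 506 (004, MORAb003), and 2499 and 726 (003, MORAb003). It reversed PDIA3 for MORAb003 against folate (0.0345) and LOXL2 for MORAb003 against 004 (-0.0212). The cause was not tested.

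Leaving out 1 array moved the counts of called genes over 91 to 922 (no folate against folate), 13 to 1175 (003 against 004), 1748 to 4345 (MORAb003 against 004), 1 to 1032 (003 against folate) and 427 to 1465 (MORAb003 against folate). More than 1.5-fold moves came from every array of the 2 extracts for no folate against folate, 003 against 004 and 003 against folate. For MORAb003 against folate they came from folate replicates 2 and 3 and MORAb003 replicates 1 and 2, and for MORAb003 against 004 from 004 replicates 1 and 3. Replicate 1 of 004 moved all 5. The first array date alone, which leaves out replicate 3, gave 0 (no folate against folate), 0 (003 against 004) and 2470 (MORAb003 against 004). Lists and pairs were recomputed without each replicate number and without replicate 1 of 004. Lists ranged over 0 to 8 (003 against 004), 2 to 10 (MORAb003 against 004) and 0 to 14 (004 against folate), and culture-level antibody lists were 12. Pairs 1.5-fold apart ranged over 883 to 2167 (no folate, 004), 1 to 2438 (folate, 004), 885 to 1848 (004, 003) and 1730 to 4576 (004, MORAb003). Pairs 2-fold apart ranged over 44 to 157 (no folate, folate), 72 to 320 (no folate, 004), 4 to 10 (no folate, 003), 0 to 229 (folate, 004), 51 to 240 (folate, 003), 65 to 178 (004, 003) and 370 to 1775 (004, MORAb003). For 004 against folate the mean of the G2/M list less that of all genes ranged over -0.278 to 0.0304 and that of the chaperones over -0.246 to 0.010001, and camera's direction for G2/M also changed without replicate 1 of 004 (-0.00535). The cause was not tested.

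At the culture level, leaving out the 003 culture gave 1684 genes for antibody and 140 for no folate, and leaving out the MORAb003 culture 52 and 140. With replicate 1 of the 004 extract also left out the ranges were 0 to 7401 and 0 to 5071. These fits have 1 residual degree of freedom, from the closeness of the folate and 004 cultures, and assume that the lone culture varies like them.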

Other observations

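Single genes outside the lists called above differed between the 003 and MORAb003 extracts, while their lists were not called. Of 15 mesenchymal and matrix genes 5 were lower with 003 and 0 higher, with ZEB1 at -1.80, MMP1 at -1.40, LOXL2 at -1.23 and VIM at -1.22, and the list had a median of 0.0796 and was not called (adjusted p = 0.189). Of the interferon response, IFIT1 differed by -1.42 and IRF9 by -1.06, with 7 of 24 genes lower and 2 higher (adjusted p = 0.484). Of 27 apoptosis regulators 4 were lower, among them FAS at -1.43 and CASP8 at -1.70, and 1 higher (adjusted p = 0.933). Of 12 antigen presentation genes PSMB10 was higher by 1.29 and B2M and HLA-B lower at -0.73 and -0.64 (adjusted p = 0.883). In these 4 lists the numbers adjusted over the list alone were the same. These values compare 2 RNA extracts whose actin 3′ to 5′ gaps were 4.02 and 2.42.

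The bacterial bioB spike read log2 8.74 ± 0.45 (SD, n = 3 arrays) in the MORAb003 extract against 10.09 to 10.82 in the other extracts.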
